A study of Mus musculus with 4 samples.

How the data were processed

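Total RNA from dendritic cells sorted out of mouse spleen was sequenced in 4 libraries, 2 from KO and 2 from WT samples. Per the labels' protocols, libraries were made with a stranded total RNA kit for very small inputs, which does not select polyadenylated RNA, so transcripts without a poly(A) tail such as most histone mRNAs are also read. The deposited table holds log2 values for 17300 Ensembl genes, already scaled between libraries by the authors. Per the submitters' processing notes, Salmon 1.10.1, DESeq2 and the mouse build GRCm39 were used, with no role or order given. The annotation and the gene filter are not given in the sources used here.

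The unit was worked out from the values. All 4 libraries share the lowest value of 8.04, and values near it are compressed, as a variance-stabilizing transform of read counts gives. Undoing such a transform from the shared lowest value alone gave normalized read counts. In the lowest genes, between 61.0% and 69.9% of these lay within 0.1 of a whole multiple of a step, chosen per library for the largest such share, of between 0.909 and 1.04. The back-transformed counts summed to 30952251 in KO A, 30274060 in KO B, 29002408 in WT 1 and 29377044 in WT 2. These sums come after scaling between libraries, so they do not give the depth of each library in reads. Because low values are compressed, a log2 difference understates the fold of a weakly expressed gene, and the ratio of mean back-transformed counts is given beside it for some of the named genes.

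The KO columns of the table carry other numbers than the titles of the KO samples. They were therefore taken only as the KO group and are called KO A and KO B. The labels give neither the deleted gene, the sex of the animals nor whether samples of a group came from separate animals. All columns of the table begin with Allo, which the sources used here do not explain, so whether the cells came from stimulated or unstimulated animals is not known. The p-values then measure only the spread between these samples, which may be technical.

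Gene symbols came from GENCODE M21, an annotation of an older build than the authors'. It was used only for names (17289 of 17300 identifiers matched, 11 did not) and for the order of neighbouring genes, and no coordinates are given. In the table, 14 genes had values identical to another gene in all libraries. Symbols of near-identical copies, such as those of globin, histone, ribosomal protein and NK receptor genes, stand for reads that the authors' counting could have split between copies.

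Genes entered the test when their mean over the 4 libraries was at least 1 log2 unit above the lowest value, which left 11864. KO was compared with WT in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation, an intensity trend, a two-sided test and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. Moderation gave 6.48 total degrees of freedom. Gene lists for dendritic cell functions, subsets, other spleen cell types, stress, metabolism and RNA quality were compared with all other tested genes by limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over the 42 lists with at least 5 tested members. Lists of nuclear RNA and of sex-linked genes had fewer tested members. The count of members past the threshold is given over all genes and adjusted over the list alone. Of the 22 lists past the threshold with camera, 0 passed when the correlation was estimated from the residuals (smallest adjusted p = 0.590, and 1 list with an unadjusted p under 0.05). In that form camera also takes its degrees of freedom from the residuals of 4 libraries, so few lists can pass. The pan dendritic cell list missed the threshold there with an estimated correlation of -0.0028, below the preset 0.01. For that list the values therefore do not show that correlation between genes removes the result. Estimates differed between lists: 0.909 for erythroid, 0.883 for immediate early, 0.872 for histone and 0.513 for NK genes. They were -0.026 for glycolysis and 0.027 for T cell genes. Where the estimate was high, the camera p-values assume far less correlation than was estimated. With fry, a rotation test of whether a list's own genes move on balance in 1 direction, 2 passed: pan dendritic cell identity (adjusted p = 0.0293) and glycolysis (adjusted p = 0.0119).

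The test, the filter, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the log2 of the back-transformed count plus 1, added after seeing the data. Named genes were the 12 with the largest difference in each direction among those past the threshold whose KO libraries both lay on 1 side of both WT libraries. Unnamed gene models and antigen receptor segments were counted and passed over (1 higher, 3 lower). From each list at most 4 members past the threshold were named, by smallest p, with 2 places per direction and any unused places given to the other. Some genes that these rules select are not reported here. Other genes named in the text are said to be chosen after their values were seen. Alternatives were no filter, a filter of 2 log2 units, quantile normalization, median centring, moderation without the trend or with robust settings, a false discovery rate of 0.1, a minimum difference of 1 log2 unit, and leaving out each library in turn.

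The fit was tested on simulated data made from the 11864 genes of KO against WT. It recovered 11 of 50 genes shifted by 0.5 log2 units, 47 of 50 shifted by 1, 50 of 50 shifted by 1.5 and 49 of 50 shifted by 2, with 5 of 11664 unchanged genes past the threshold. A list lowered by 0.5 was called, and 0 of the other lists were. The simulated genes varied independently and no library stood apart, whereas the erythroid list had an estimated correlation of 0.909 in the data. The simulation therefore does not measure false calls of genes or lists in these data. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.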

Results

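Dendritic cells are the antigen-presenting cells that start T cell responses. Their RNA was measured in 2 KO and 2 WT samples from mouse spleen, with between 29002408 and 30952251 back-transformed counts per library. The series title concerns Siglec-E, a receptor for sialic acid that inhibits myeloid cells, and its part in the activation of antigen-presenting cells and in transplant rejection. Read with that title, the comparison of KO with WT asks which genes of sorted splenic dendritic cells differ when the receptor is lost, in animals whose treatment is not known from the sources used here.

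Siglece (ENSMUSG00000030474), the gene of Siglec-E, stood at 8.92 in KO A and 8.96 in KO B, against 10.38 in WT 1 and 10.14 in WT 2 (log2 values). It fell by 1.32 (SE 0.107, adjusted p = 0.0138), from a mean of 763 normalized counts in WT to 106 in KO, 7.18-fold lower. The KO libraries had more RNA of immediate early genes, with Egr1, Atf3 and Dusp1 among those past the threshold, and of red cell genes, with Slc4a1 and Hbb-bt among them (adjusted p = 0.609 and 0.624 with an estimated correlation for the lists). Genes that define conventional dendritic cells, among them Flt3, Zbtb46 and Dpp4, and the class II regulator Ciita were lower (adjusted p = 0.590 with an estimated correlation for the pan dendritic cell list). Lists of NK cell, macrophage, monocyte and neutrophil markers were higher in the same libraries (adjusted p = 0.609 with an estimated correlation for each). The neutrophil list's median was 0.21 against WT 1 and 1.15 against WT 2.

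Of 11864 genes tested, 822 passed the threshold, 557 higher and 265 lower in KO. With quantile normalization the split was 366 higher and 282 lower, so 56.5% of calls were higher in place of 67.8%. A difference of at least 1 log2 unit was found for 96 of the 822, 87 higher and 9 lower. The first principal component held 70.1% of the variance, with KO A at -14.2 and KO B at -16.9 against WT 1 at 19.3 and WT 2 at 11.8. Group labels given at random would match a split into these pairs in 33.3% of cases. Without KO A, 0 genes passed in limma (2508 had an unadjusted p under 0.05). Without KO B 3 passed, all lower and 0 of them among the 822 (2448 had an unadjusted p under 0.05). These 3 were the Y-linked genes Ddx3y, Eif2s3y and Kdm5d, named after their values were seen, in which KO A stood apart: Ddx3y was at 8.74 there against 11.82 to 12.13 elsewhere, and Eif2s3y at 8.54 against 11.12 to 11.24. In back-transformed counts Ddx3y was at 64.5 in KO A against 3102 to 3979 elsewhere, and Eif2s3y at 32.2 against 1725 to 1921. Kdm5d was at 551 against 2089 to 2908. KO A thus held far less Y-linked RNA than the other 3 libraries. The labels give no sex, and these values do not tell female from mixed material. Whether such a difference in sex is a part of the KO and WT differences or of the spread within KO was not tested and is not excluded.

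**Figure D1:**
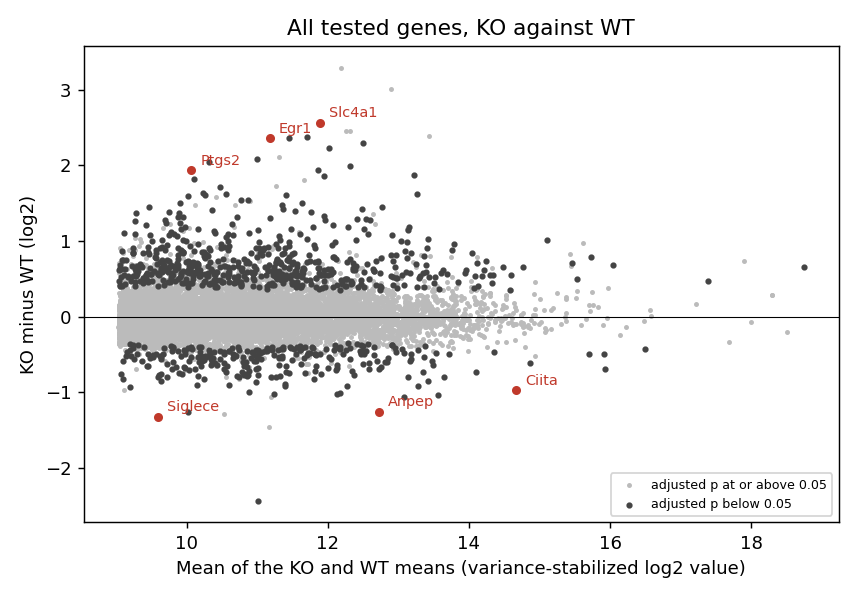
Each point is a tested gene, with the mean of the group means on the x axis and KO minus WT on the y axis, both in log2 units. The 822 genes past the threshold are dark, and 557 of them lie above 0.

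Slc4a1, the anion exchanger of the red cell membrane, was at 13.17 ± 0.29 in KO and 10.61 ± 1.34 in WT (SD, n = 2 each), a difference of 2.56 (SE 0.543, adjusted p = 0.0450). Its counts were 6.12-fold higher. Hbb-bt, a beta globin, rose by 2.36 (SE 0.509, adjusted p = 0.0466), and Sptb, a spectrin of the red cell skeleton, by 1.94 (SE 0.299, adjusted p = 0.0241). Atf3, a stress-induced transcription factor, rose by 2.37 (SE 0.516, adjusted p = 0.0476) and Egr1, an early growth response factor, by 2.36 (SE 0.274, adjusted p = 0.0147), with 7.93-fold more counts. Dusp1, a MAP kinase phosphatase, rose by 2.29 (SE 0.451, adjusted p = 0.0389), the nuclear receptor Nr4a2 by 2.05 (SE 0.365, adjusted p = 0.0314), and Rgs1, a regulator of G protein signalling, by 1.99 (SE 0.327, adjusted p = 0.0263). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 1.93 (SE 0.172, adjusted p = 0.0147), 10.1-fold in counts. Zfp36, which destabilizes cytokine mRNAs, rose by 1.87 (SE 0.292, adjusted p = 0.0246), and Ppp1r15a, a stress-induced phosphatase subunit, by 1.86 (SE 0.318, adjusted p = 0.0279). Without WT 1 the differences of Slc4a1, Atf3, Hbb-bt and Dusp1 were 1.62, 1.46, 1.49 and 1.51, below those of Egr1 and Ptgs2 (1.96 and 1.69), so the order by size depends on WT 1.

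Among the genes that fell, besides Siglece, was Anpep, the aminopeptidase CD13, with 12.09 ± 0.098 in KO and 13.35 ± 0.024 in WT (SD, n = 2 each), a fall by 1.26 (SE 0.0850, adjusted p = 0.0138) and 2.57-fold in counts. Il6st, the signalling subunit of the interleukin 6 receptor family, fell by 1.07 (SE 0.0920, adjusted p = 0.0147). Rgs12 fell by 1.02 (SE 0.0822, adjusted p = 0.0138), Asb2, a ubiquitin ligase subunit, fell by 1.01 (SE 0.125, adjusted p = 0.0171), and St8sia6, a sialyltransferase, was 2.51-fold lower in counts (SE of the log2 difference 0.144, adjusted p = 0.0211). Ciita, the master regulator of MHC class II genes, went from 15.16 ± 0.062 in WT to 14.18 ± 0.072 in KO (SD, n = 2 each), a fall by 0.98 (SE 0.0866, adjusted p = 0.0147). The lysophosphatidic acid receptor Lpar1 fell by 0.94 (SE 0.108, adjusted p = 0.0147), which was 6.03-fold in counts at a low level. Cyp4f16 and Dscam each fell by 0.92 (adjusted p = 0.0147 and 0.0257), and Dpp4, the peptidase CD26, fell by 0.91 (SE 0.0763, adjusted p = 0.0138). Rps7 fell by 1.04 (SE 0.105, adjusted p = 0.0147), but its value is uncertain, since pseudogene copies can share its reads.

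**Figure D2:**
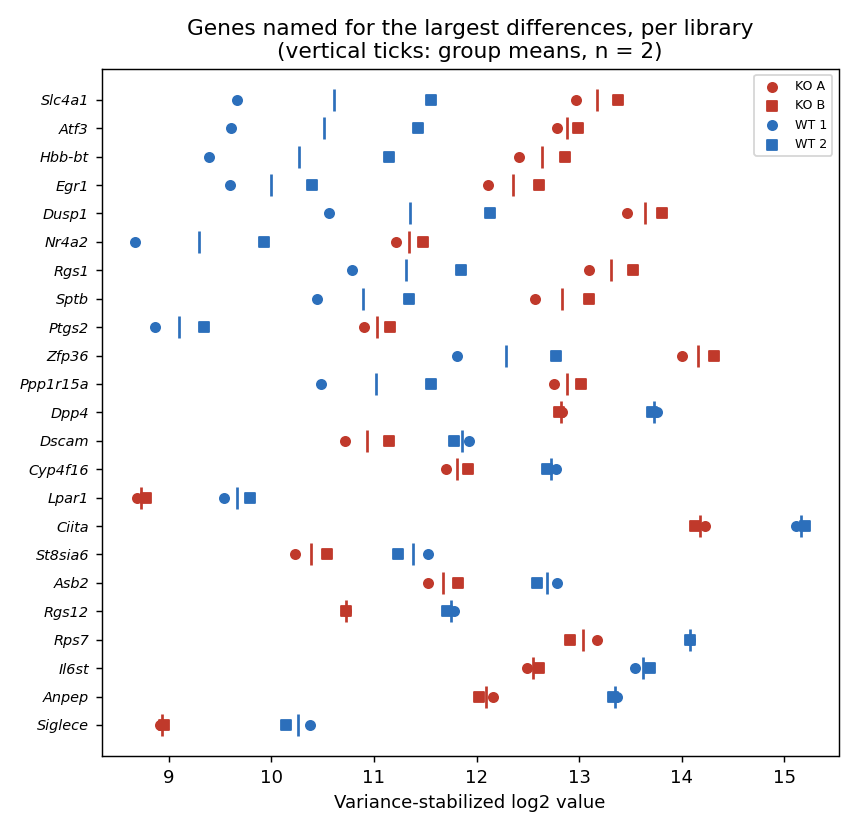
Variance-stabilized log2 values of the genes named for the largest differences among those past the threshold, with KO libraries in red, WT libraries in blue and vertical ticks at the group means (n = 2). Siglece lies at 8.92 and 8.96 in KO and at 10.14 and 10.38 in WT, and the WT libraries lie farther apart in the genes that rose than in those that fell.

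Dendritic cell identity genes fell as a list. Of 17 pan dendritic cell genes tested, 0 rose, 12 fell and 5 did not pass, and 14 fell when adjusted over the list alone. The median difference was -0.60 and the camera adjusted p was 1.36e-13 (adjusted p = 0.590 with an estimated correlation). Besides Dpp4 and Ciita, Flt3, the growth factor receptor of dendritic cells, fell by 0.73 (adjusted p = 0.0147) and Zbtb46, a transcription factor of conventional dendritic cells, fell by 0.68 (adjusted p = 0.0155). Of 22 conventional DC1 markers 5 fell, 1 rose and 16 did not pass; adjusted over the list alone 12 fell and 1 rose. Their median was -0.37, at -0.21 against WT 1 and -0.59 against WT 2 (camera adjusted p = 3.75e-06; adjusted p = 0.624 with an estimated correlation). Tlr11 fell by 0.68 (adjusted p = 0.0191), Btla fell by 0.56 (adjusted p = 0.0213) and Wdfy4, needed for cross-presentation, fell by 0.70 (adjusted p = 0.0215), while Cd24a rose by 0.66 (adjusted p = 0.0199).

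Subset lists other than conventional DC1 did not pass. Among 24 conventional DC2 markers 2 rose, 3 fell and 19 did not pass, and adjusted over the list alone 5 rose and 7 fell, with a median of -0.10, a mean near 0 and a camera adjusted p of 0.452. Klf4 rose by 1.19 (adjusted p = 0.0138) and Esam fell by 0.56 (2.70-fold in counts, adjusted p = 0.0250). Of 26 plasmacytoid markers 1 rose, 1 fell and 24 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.224). Atp1b1 rose by 0.75 (adjusted p = 0.0482) and Cadm3 fell by 0.61 (adjusted p = 0.0295). This list depended on the KO library: it was lower without KO A (adjusted p = 0.0278) and higher without KO B (adjusted p = 5.28e-08). In the list of mature or migratory dendritic cells 4 of 26 fell and 22 did not pass, with 7 lower when adjusted over the list alone and a median of -0.25 (camera adjusted p = 0.000183; adjusted p = 0.624 with an estimated correlation). The median was -0.40 in KO A and -0.10 in KO B against the WT mean. Relb, an NF-kB subunit, fell by 0.71 (adjusted p = 0.0191), and Il4i1, an amino acid oxidase, fell by 0.80 (adjusted p = 0.0199).

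Of 19 MHC class II genes tested 11 fell, 1 rose and 7 did not pass, and adjusted over the list alone 13 fell and 1 rose. Their median was -0.42 (camera adjusted p = 4.68e-06; adjusted p = 0.609 with an estimated correlation). In the same libraries the pan dendritic cell list had a median of -0.60 with 12 of 17 genes lower, and the NK, erythroid, macrophage and monocyte lists had medians of 0.67, 1.38, 0.61 and 0.50. H2-Oa, part of a class II loading modulator, fell by 0.64 (adjusted p = 0.0199) and H2-Eb2 fell by 0.77 (adjusted p = 0.0246). The protease gene Ctsb rose by 0.55 (adjusted p = 0.0389). Chosen after their values were seen, H2-Aa fell by 0.49 (adjusted p = 0.0324), H2-Ab1 fell by 0.43 (adjusted p = 0.04995, just under the threshold) and Cd74 differed by -0.34 (adjusted p = 0.107). MHC class I and cross-presentation genes did not pass as a list: 0 rose, 1 fell (Wdfy4) and 26 did not pass, against 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.906).

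Co-stimulatory genes did not pass as a list (camera adjusted p = 0.251). Of 16, 0 rose, 3 fell and 13 did not pass, and adjusted over the list alone 1 rose and 5 fell. Cd40 fell by 0.69 (adjusted p = 0.0162), Icosl, the ligand of ICOS, fell by 0.78 (adjusted p = 0.0202) and Cd80, a ligand of CD28, fell by 0.54 (adjusted p = 0.0453). Cd86 and Cd83, chosen after their values were seen, differed by 0.19 (adjusted p = 0.403) and -0.05 (adjusted p = 0.823). In the Siglec family 1 of 6 rose, 2 fell and 3 did not pass; adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.399). Cd33 rose by 0.83 (adjusted p = 0.0279), and besides Siglece the B cell receptor inhibitor Siglecg fell by 0.80 (adjusted p = 0.0241). Whether the changes of Cd33 and Siglecg come from loss of the receptor or from how Siglece was targeted was not tested.

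Immediate early genes, which are switched on within minutes by stimulation or by tissue dissociation, rose as a list. Of 28 tested 23 rose, 0 fell and 5 did not pass, and 28 rose when adjusted over the list alone. The median was 1.26 (camera adjusted p = 7.93e-21; adjusted p = 0.609 with an estimated correlation). Klf4 rose by 1.19 and Fosl2 by 1.38 (adjusted p = 0.0138 each). Fos, Fosb and Jun, chosen after their values were seen, did not pass over all genes: Fos was at 14.30 and 14.51 in KO, at 10.12 in WT 1 and at 12.66 in WT 2, a difference of 3.01 (SE 0.712, adjusted p = 0.0567), with 3.29 (adjusted p = 0.0754) for Fosb and 2.39 (adjusted p = 0.0803) for Jun. WT 1 was the lowest library in these too: Fosb was at 13.71 and 13.97 in KO and 12.10 in WT 2, with a WT mean of 10.55, and Jun at 14.67 and 14.59 in KO, 11.07 in WT 1 and 13.40 in WT 2. The WT libraries differed in this list by a median of 0.46, with WT 2 higher.

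NF-kB targets and inflammatory cytokines moved both ways, with 13 of 33 higher, 3 lower and 17 not past the threshold, and 15 higher and 6 lower adjusted over the list alone. The median was 0.12 and the mean 0.37 (camera adjusted p = 0.0325; adjusted p = 0.624 with an estimated correlation). The call ended with the filter of 2 log2 units (adjusted p = 0.186), with log2 of the count plus 1 (adjusted p = 0.0505) and without KO B (adjusted p = 0.0769). Tnfaip3, a brake on NF-kB, rose by 1.27 (adjusted p = 0.0138), and Traf1 fell by 0.60 (adjusted p = 0.0199). Heat shock genes showed 3 of 18 higher, 0 lower and 15 not past the threshold, with the same counts adjusted over the list alone and a median of 0.46 (camera adjusted p = 0.000374; adjusted p = 0.656 with an estimated correlation). Dnajb4 rose by 0.67 (adjusted p = 0.0246) and Bag3 by 0.48 (adjusted p = 0.0410). The median was 0.58 in KO A and 0.21 in KO B against the WT mean, and 0.60 against WT 1 and 0.19 against WT 2, and the call ended without KO A (adjusted p = 0.164). Hspa1a, chosen after its values were seen, ran from 10.79 in WT 1 and 13.12 in WT 2 to 14.26 in KO A and 12.38 in KO B (adjusted p = 0.370).

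Interferon response lists did not pass. Of 47 type I interferon genes 3 rose, 0 fell and 44 did not pass, and 2 rose when adjusted over the list alone (camera adjusted p = 0.519). Rsad2, an antiviral enzyme, rose by 1.05 (adjusted p = 0.0199) and Cmpk2 by 0.54 (adjusted p = 0.0277). The list was lower without KO A (adjusted p = 0.0235) and higher without KO B (adjusted p = 0.000317). Of 27 interferon gamma response genes 1 rose, 2 fell and 24 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.512). Their median of -0.02 and mean of 0.01 differed in sign, and the list was lower without WT 1 (adjusted p = 0.0330). Socs3 rose by 0.91 (adjusted p = 0.0233) and Jak2 fell by 0.48 (adjusted p = 0.0279).

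Markers of several other cell types were higher in the KO libraries, in which dendritic cell genes were lower, while the B cell, platelet and stromal lists did not pass (camera adjusted p = 0.339, 0.399 and 0.440). Of 21 NK cell markers 17 rose, 0 fell and 4 did not pass, and adjusted over the list alone 18 rose and 1 fell, with a median of 0.67 (camera adjusted p = 7.72e-12; adjusted p = 0.609 with an estimated correlation). The granzymes Gzma and Gzmb rose by 1.16 and 0.87, the transcription factor Eomes by 0.91 and the receptor Ncr1 by 0.93 (adjusted p = 0.0147 each). Of 23 erythroid markers 13 rose, 0 fell and 10 did not pass, and 21 rose when adjusted over the list alone. Their median was 1.38, at 1.76 against WT 1 and 0.93 against WT 2 (camera adjusted p = 5.06e-12; adjusted p = 0.624 with an estimated correlation). Car1, a carbonic anhydrase, rose by 1.16 (adjusted p = 0.0319) and Fech, the last enzyme of haem synthesis, by 0.99 (adjusted p = 0.0198). Erythroid list genes held 0.227% and 0.328% of back-transformed counts in KO A and KO B, against 0.0424% in WT 1 and 0.120% in WT 2.

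Macrophage markers rose in 6 of 21 genes, with 0 lower and 15 not past the threshold, and in 16 when adjusted over the list alone (median 0.61, camera adjusted p = 2.27e-09; adjusted p = 0.609 with an estimated correlation). The list was at 0.33 in KO A and 0.81 in KO B against the WT mean. Apoe rose by 0.99 (adjusted p = 0.0138), the haem oxygenase gene Hmox1 by 1.07 (adjusted p = 0.0147) and the complement gene C1qb by 0.72 (adjusted p = 0.0302). Monocyte markers rose in 9 of 25 genes, with 0 lower and 16 not past the threshold; adjusted over the list alone 14 rose and 1 fell (median 0.50, camera adjusted p = 7.18e-07; adjusted p = 0.609 with an estimated correlation). Cebpb rose by 1.21 and Fn1 by 0.90 (adjusted p = 0.0147 each), and Nr4a1, also an immediate early gene, by 1.62 (adjusted p = 0.0173). Of 22 neutrophil markers 6 rose, 0 fell and 16 did not pass, and 9 rose when adjusted over the list alone (camera adjusted p = 1.69e-08; adjusted p = 0.609 with an estimated correlation). Trem1 rose by 1.02 (4.14-fold in counts) and Hdc, which is also in the basophil list, by 1.48 (adjusted p = 0.0147 each). However, the neutrophil list's median of 0.79 was 0.21 against WT 1 and 1.15 against WT 2. Its genes held 0.977% and 0.940% of counts in KO A and KO B, against 0.883% in WT 1 and 0.344% in WT 2. S100a8, chosen after its values were seen, was at 12.95 in WT 2 and between 14.48 and 14.54 in the other libraries (adjusted p = 0.324). Basophil and mast cell markers showed 4 of 9 higher, 1 lower and 4 not past the threshold, and 6 higher and 1 lower adjusted over the list alone (median 0.46, camera adjusted p = 0.000842; adjusted p = 0.624 with an estimated correlation). The list was at 0.33 in KO A and 0.72 in KO B against the WT mean. Gata2 rose by 0.91 (3.65-fold in counts, adjusted p = 0.0263) and Kit, which dendritic cells also express, fell by 0.69 (adjusted p = 0.0253).

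T cell, plasma cell and B cell markers were also tested. T cell markers rose in 4 of 17 genes, with 0 lower and 13 not past the threshold; adjusted over the list alone 8 rose and 1 fell (median 0.24, camera adjusted p = 0.00179; adjusted p = 0.609 with an estimated correlation). Lck rose by 0.77 (adjusted p = 0.0206) and Cd28 by 0.66 (3.15-fold in counts, adjusted p = 0.0215). Plasma cell markers rose in 2 of 15 genes, with 0 lower and 13 not past the threshold, and in 4 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0139; adjusted p = 0.609 with an estimated correlation). Igha rose by 2.23 (adjusted p = 0.0151) and Jchain, the joining chain of secreted antibodies, by 1.03 (adjusted p = 0.0323). The plasma cell median was 0.38 in KO A and 0.02 in KO B against the WT mean, and the call ended without KO A (adjusted p = 0.279). Of 18 B cell markers 2 rose, 0 fell and 16 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.339). Igkc rose by 1.03 (adjusted p = 0.0147) and Ighm by 0.37 (adjusted p = 0.0465), but the list's direction turned with the library left out: higher without KO A (adjusted p = 0.0346) and without WT 1 (adjusted p = 0.000370), and downward without KO B (adjusted p = 0.868) and without WT 2 (adjusted p = 0.135). Its median was -0.18 against WT 1 and 0.30 against WT 2.

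**Figure D3:**
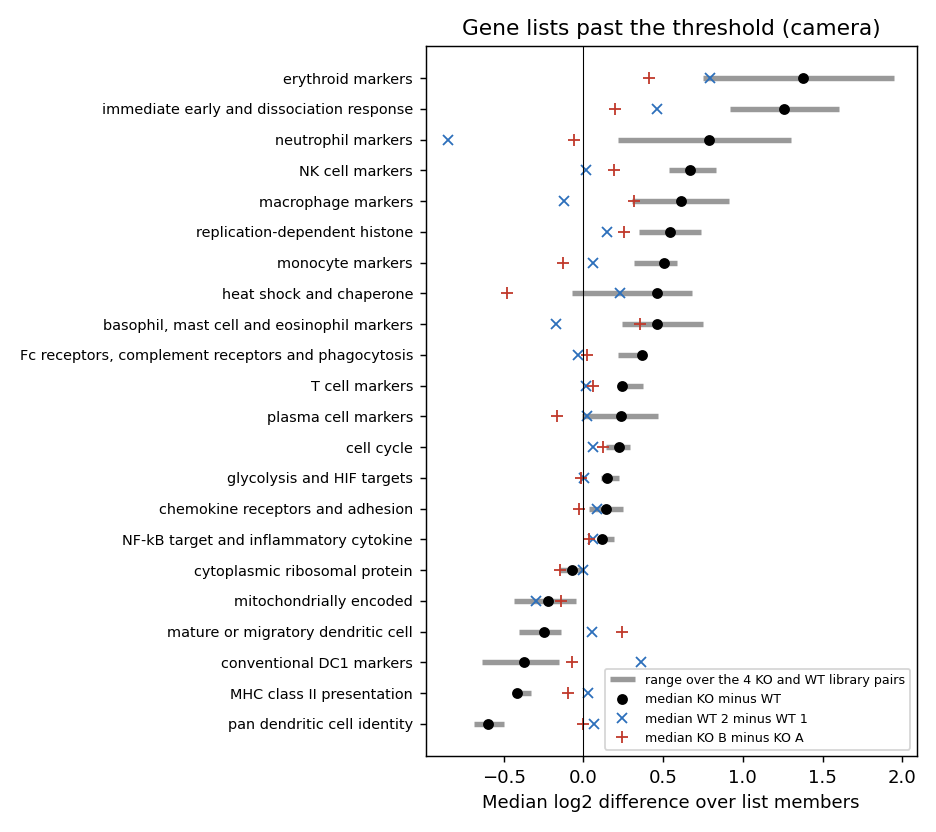
Median log2 difference over the members of each list past the threshold, with black points for KO minus WT, grey bars for the range over the 4 KO and WT library pairs, and crosses and plus signs for the differences within WT and within KO. The pan dendritic cell list lies at -0.60 and the erythroid list at 1.38, and in the neutrophil list the WT libraries differ by -0.85.

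Replication-dependent histone genes rose in 23 of 45, with 0 lower and 22 not past the threshold, and in 43 when adjusted over the list alone (median 0.54, camera adjusted p = 7.93e-21; adjusted p = 0.624 with an estimated correlation). Hist1h4d rose by 0.70 (adjusted p = 0.0191) and Hist1h2bn by 0.77 (adjusted p = 0.0241), though near-identical copies make single histone genes uncertain. Most histone mRNAs lack a poly(A) tail, and whether RNA without such a tail differed between the groups as a whole was not tested. Cell cycle genes rose in 5 of 45, with 0 lower and 40 not past the threshold; adjusted over the list alone 15 rose and 1 fell (median 0.22, camera adjusted p = 1.26e-06; adjusted p = 0.624 with an estimated correlation). Tubb4b rose by 0.55 (adjusted p = 0.0322) and Ccne1, a cyclin of S phase entry, by 0.45 (adjusted p = 0.0381). Erythroid, NK cell and macrophage lists had medians of 1.38, 0.67 and 0.61 in the same libraries.

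Glycolysis and HIF target genes rose in 5 of 26, with 0 lower and 21 not past the threshold; adjusted over the list alone 9 rose and 1 fell (median 0.15, camera adjusted p = 0.000849; adjusted p = 0.609 with an estimated correlation). Slc16a3, a lactate exporter, rose by 0.91 (adjusted p = 0.0199) and the hexokinase Hk1 by 0.62 (adjusted p = 0.0213). Of 72 nuclear genes of oxidative phosphorylation 0 passed with limma over all genes or adjusted over the list alone (4 had an unadjusted p under 0.05), and the list had a median of -0.01 (camera adjusted p = 0.519). It was lower without KO A (adjusted p = 0.00770). Of 13 mitochondrially encoded genes 0 passed with limma by either count (1 had an unadjusted p under 0.05), while the list was lower (median -0.22, camera adjusted p = 0.00375; adjusted p = 0.676 with an estimated correlation). Its median was -0.36 against WT 1 and -0.08 against WT 2, and the call ended without WT 1 (adjusted p = 0.304). Of 76 ribosomal protein genes 1 fell (Rps7) and 75 did not pass, as when adjusted over the list alone. The list's median was -0.07, at -0.003 in KO A and -0.15 in KO B against the WT mean (camera adjusted p = 0.00179; adjusted p = 0.828 with an estimated correlation), and the call ended without KO B (adjusted p = 0.600).

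Receptors of phagocytosis rose in 6 of 29 genes and fell in 2, with 21 not past the threshold; adjusted over the list alone 13 rose and 2 fell (median 0.37, camera adjusted p = 0.000909; adjusted p = 0.609 with an estimated correlation). Of the 29 genes 13 are in another list, and the macrophage, monocyte and neutrophil lists had medians of 0.61, 0.50 and 0.79 in the same libraries. Clec4e, a receptor for fungal and mycobacterial lipids, rose by 1.32 and Fcgr3, an IgG receptor, by 0.69 (adjusted p = 0.0147 each). The integrin Itgax, which encodes CD11c, fell by 0.73 (adjusted p = 0.0206) and Clec9a, a receptor for dead cells, fell by 0.58 (adjusted p = 0.0319). Chemokine receptor and adhesion genes rose in 5 of 26 and fell in 2, with 19 not past the threshold; adjusted over the list alone 7 rose and 2 fell (median 0.14, camera adjusted p = 0.0300; adjusted p = 0.620 with an estimated correlation). The median was 0.23 against WT 1 and 0.09 against WT 2. Cxcr4 rose by 0.72 (adjusted p = 0.0147) and Ccr6 fell by 0.75 (2.86-fold in counts, adjusted p = 0.0180). The list's call ended without KO A (adjusted p = 0.0700) and without WT 1 (adjusted p = 0.281).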

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

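The log2 of the back-transformed count plus 1 was chosen after seeing the data, and the other alternatives before. Against 822 genes, 648 to 866 passed with no filter, the filter of 2 log2 units, quantile normalization, median centring, other moderation or log2 of the count plus 1. Of the 822, 615 remained with quantile normalization, which lowered the genes higher in KO to 366 and raised those lower to 282, and 618 to 778 in the other 6; the cause of this shift was not tested. A minimum of 1 log2 unit left 96 genes, 87 higher and 9 lower, and a false discovery rate of 0.1 gave 1579, 1013 higher and 566 lower, both by construction. Leaving out 1 library in turn gave 0 to 820 genes, 0 to 620 higher and 0 to 200 lower in limma. There were 0 without KO A (2508 at an unadjusted p under 0.05), 3 without KO B (2448), 646 without WT 1, of which 468 were among the 822 and 167 were lower, and 820 without WT 2, of which 601 were among the 822. With 1 library left in a group, that library is assumed to vary like the other group, and the fit has fewer samples. Siglece stayed lower in every alternative run, with differences of -1.44 to -1.20 when 1 library was left out. It missed the threshold without KO A (adjusted p = 0.0545) and without KO B (adjusted p = 0.0851), where its adjusted p over all alternatives ranged from 0.000139 to 0.0851. It was not tested with the filter of 2 log2 units. Of 127 other named genes 0 reversed in any alternative, 127 missed the threshold without KO A and 127 without KO B, 29 without WT 1, 14 without WT 2, 18 with quantile normalization and 16 with log2 of the count plus 1. Of the lists, 20 to 24 passed in the alternatives against 22, apart from 0 with an estimated correlation and 2 with fry. These 2 tests differ in construction from camera with the preset correlation. With 2 libraries per group the estimated correlation rests on few residuals, which also set the degrees of freedom there, so few lists can pass. The fry test does not compare a list with other genes. Of the 22 lists 16 passed in every camera alternative run with the preset correlation, 6 missed it in 1 to 3 of them (NF-kB, chemokine receptors, plasma cell, heat shock, mitochondrial and ribosomal), and 0 changed direction. No paired analysis was possible because the KO columns carry other numbers than the KO titles, so no KO library shares a number with a WT library. Low values are compressed, which limits the weakest genes. Small differences are often missed with 2 libraries per group: at a shift of 0.5 log2 units 11 of 50 simulated genes, drawn from all tested genes, were recovered.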

Other observations

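The tests of explanations in this part, the limits used in them and the choice of genes outside the naming rule were made after the results were seen. The gene lists and their tests were planned. Pattern recognition genes moved both ways, with 5 of 42 higher, 3 lower and 34 not past the threshold, and 7 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.695). The list's median of -0.04 and mean of 0.01 differed in sign. Tlr2, a receptor for bacterial lipoproteins, rose by 0.65 (adjusted p = 0.0206), and Tlr1, its partner, fell by 0.77 (adjusted p = 0.0147). Lysosome and autophagy genes had 6 of 40 higher, 2 lower and 32 not past the threshold, and 8 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.224; adjusted p = 0.0336 and higher without KO B). Ctsd, a lysosomal protease, rose by 0.72 (adjusted p = 0.0147) and the lipase gene Lipa fell by 0.40 (adjusted p = 0.0389). Apoptosis and p53 genes had 4 of 32 higher, 0 lower and 28 not past the threshold, and 8 higher adjusted over the list alone (camera adjusted p = 0.336), with a median of -0.02 against a mean of 0.12, and camera pointed upward. Gadd45a rose by 0.86 (adjusted p = 0.0147) and the death gene Bcl2l11 by 0.73 (adjusted p = 0.0485; 0.48 and not past the threshold without WT 1). Of 25 genes of the unfolded protein and integrated stress response 2 rose, 0 fell and 23 did not pass, and 4 rose when adjusted over the list alone (camera adjusted p = 0.149). This list was higher with no filter (adjusted p = 0.0342), without KO B (adjusted p = 0.00378) and without WT 2 (adjusted p = 0.00646). Atf4, the transcription factor of that response, rose by 0.79 (adjusted p = 0.0363). Cholesterol and fatty acid synthesis had 2 of 29 higher, among them Insig1 by 0.52 (adjusted p = 0.0311), 0 lower and 27 not past the threshold, with the same counts adjusted over the list alone (camera adjusted p = 0.336).

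The list of sialic acid metabolism holds genes that make the ligands of Siglec receptors and others, the neuraminidases, that remove sialic acid. It had 1 of 23 higher, 1 lower and 21 not past the threshold, and 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.573). St3gal6 rose by 0.85 (adjusted p = 0.0411), opposite to St8sia6. Other inhibitory receptors had 1 of 19 higher, 2 lower and 16 not past the threshold, and 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.779). The median of -0.01 and the mean of 0.01 differed in sign. Lilrb4a rose by 0.82 (adjusted p = 0.0242) and Cd72 fell by 0.40 (adjusted p = 0.0451). T cell polarising genes had 1 of 18 higher, Rara by 0.42 (adjusted p = 0.0331), 1 lower, Il4i1, and 16 not past the threshold; adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.503). Progenitor markers had 1 of 15 higher, Gata2, 1 lower, Kit, and 13 not past the threshold, the same as adjusted over the list alone (camera adjusted p = 0.262). Of 7 platelet and 5 stromal markers 0 passed with limma by either count (2 and 1 had an unadjusted p under 0.05; camera adjusted p = 0.399 and 0.440), and the platelet list was higher with no filter (adjusted p = 0.0175). Of the RNA quality list Lars2 was tested and differed by 0.74 (adjusted p = 0.0531). It had 318676 and 307716 counts in KO A and KO B, against 222579 and 158199 in WT 1 and WT 2. The 10 most abundant genes of each library held 9.52% and 8.93% of counts in KO A and KO B, against 8.53% and 8.05% in WT 1 and WT 2. A difference in RNA quality between the groups was not tested. The sex-linked list had 4 tested genes, all lower in KO A than in the other 3 libraries: besides Ddx3y and Eif2s3y, Kdm5d was at 9.98 against 11.34 to 11.74 and Uty was at 9.66 against a highest value of 11.24.

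Markers of NK, red and myeloid cells were higher and dendritic cell genes lower in the same KO libraries. If each list's RNA came only from its own cells, an equal rise of other cell types would raise B and NK markers alike. Under the same condition an equal loss of all dendritic cell subsets would lower subset markers as much as pan dendritic cell genes. The first was not met in the medians: the highest of the 4 KO and WT pair medians of the B cell list was 0.435, below the lowest of the NK list, 0.537 (0.459 and 0.556 over members in no other list). As shares of counts both lists were higher in KO. B genes held 0.138% and 0.165% in KO A and KO B, against 0.129% and 0.109% in WT 1 and WT 2. NK genes held 0.121% and 0.149%, against 0.0907% and 0.0883%. The comparison bears only on an equal rise. A lower share of dendritic cells with unequal carry-over of other cells was not tested and stays open. The second was not met either: the lowest pair median of the DC2 and plasmacytoid lists was -0.248, above the highest of the pan dendritic cell list, -0.495. Over members in no other list (8 of 24 DC2, 20 of 26 plasmacytoid and 11 of 17 pan genes) it was -0.248 against -0.466. The plasmacytoid median differed by -0.54 between KO libraries. Most DC2 genes are shared with other lists, such as Tbx21 with the NK list, and the pan list holds genes of conventional dendritic cells such as Zbtb46. These lists therefore cannot exclude a lower share of all subsets. A lower share of DC1 alone also stays open, since its pair medians of -0.635 to -0.152 reach into the pan range of -0.689 to -0.495. Red cell carry-over that varies between libraries may account for part of the erythroid rise: 0 of its 23 genes are in another list, the list differed between WT libraries by 57.4% of the KO and WT difference, little above the limit of 50% set for this, and globin genes held 0.0861% and 0.134% of counts in KO against 0.00565% and 0.0386% in WT. For NK cells the within-group difference was 28.9%, between that limit and the lower limit of 10%, so carry-over past the sort, whose gate is not given in the sources used here, and genotype, which was not tested, cannot be told apart with 2 libraries per group.

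Immediate early genes were higher in both KO libraries, and WT 2 lay above WT 1. Handling during dissociation and sorting that differed between libraries could raise these genes in whichever sample was kept longer. In medians over its members, the list differed within a group by at most 36.5% of the KO and WT difference, between the limits of 10% and 50%. Single members varied around this. Jun was at 11.07 in WT 1 and 13.40 in WT 2, against 14.67 and 14.59 in KO. Klf4 was at 11.61 in WT 1 and 11.78 in WT 2, against 12.85 and 12.92 in KO. Of the list's 28 genes 2 are in another list, and 23 lay above the median gene in WT. Handling and genotype, which was not tested, cannot be told apart here, since no label gives the order or time of sample preparation.

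A segment from another strain left around a targeted gene could bring changed genes beside Siglece. Of the 60 tested genes on either side, 10 of 120 (8.33%) passed the threshold, 5 higher and 5 lower, against 811 of 11734 (6.91%) of the other tested genes with a known place (Fisher's exact p = 0.472, two-sided). A surplus beside Siglece was not found, which does not exclude a short segment or a few genes changed in this way. The Siglec family genes Cd33 and Siglecg, which passed the threshold, were not examined separately for this.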
